A study of Mus musculus with 8 samples.

How the data were processed

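Total RNA from 8 mouse kidney samples was measured on single-colour Illumina bead arrays, with 1 array per sample. The labels give 4 kidney tumors of mice with a Lin28 transgene and 4 normal kidneys as controls, call them biological replicates, and give an age of 5 weeks for replicate 1 of each group and 4 months for replicates 2 to 4. RNA was taken up in Trizol, cleaned and treated with DNase I, and its quality was checked on a Bioanalyser, per the labels' protocols. Sex and strain of the animals, slides and scan days are not given in the sources used here.

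The values used were the deposited series values, which are probe intensities on a linear scale. Their background had already been subtracted, since between 20.2% and 28.4% of the values of each array lie below 0. The authors had also scaled the arrays, since the mean over all probes is 274 on each of them, while the medians run from 9.90 to 19.7. The software and the method of background subtraction and scaling are not given in the sources used here. A scaling to an equal mean leaves a difference between groups in the shape of the distribution in place, and it can move every gene of an array by the same factor. A second table of signals before normalization was not used, because its 16 columns have names that match no sample. The plan made before the data were examined named background correction and quantile normalization of that table with limma, and named the series values for this case.

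Intensities below 0 were set to 0, 16 was added, and log2 was taken, so the lowest possible value is 4 and fold changes of dim genes are understated. The noise of each array was estimated as a scaled median size of its values below 0, and a probe counted as above background where it exceeded 3 times the noise. The noise was 9.19 intensity units on the array of tumor 1 and between 3.56 and 5.49 on the other 7 arrays. Between 11357 probes (44.2%, control 1) and 14218 probes (55.3%, tumor 3) were above background. The number of arrays, 4 per group, limits the precision. A gene at or under background on all arrays of 1 group has only a bound there. Its change is given as "at least N-fold", the mean log2 intensity of the brighter group against the mean of the higher of limit and signal on each array of the dimmer group.

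Of the probes, 23978 carry 1 gene symbol in the platform annotation, 0 carry several and 1719 carry none. Symbols were brought up to date through the gene numbers of the GRCm38.p6 annotation, in which 23962 probes matched and 0 symbols changed. That assembly was used only for names and for which genes lie next to each other. The 10279 probes with a mean log2 value under the 40th percentile were removed and 15418 were kept. For each symbol the kept probe with the highest mean stood for the gene, which left 11413 units, 10531 of them named and 882 unnamed. Several kept probes existed for 2845 genes, of which 6 had probes called in opposite directions and 792 had only some probes called.

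Tumors and controls were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariate), with Benjamini-Hochberg adjustment over all units and a threshold of 0.05. Gene lists were tested with limma's camera, two-sided, with the inter-gene correlation preset to 0.01 and Benjamini-Hochberg adjustment over the lists with at least 3 measured members. The 33 lists, the rule for genes to be named and the designs were set before the data were examined. The lists hold 607 symbols, of which 529 have a probe and 425 were tested. Whether the tumor effect differs with age was tested as an interaction of age and group, which leaves 4 residual degrees of freedom and rests on 1 pair at 5 weeks, assumed to vary like the arrays at 4 months. The spread between arrays was compared as the mean Pearson correlation of the 6 pairs within tumors minus that of the 6 pairs within controls, with an exact permutation of the group labels over 70 assignments.

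The genes to be named were 12 fixed genes of the Lin28 pathway and of Wilms tumor, and the 5 largest rises and 5 largest falls among called genes whose groups do not overlap. For each of 15 main lists the 2 called members with the largest change in the main direction and the 1 with the largest opposite change were added, and for each of the other lists 1 member. A list with no called member gave the member with the smallest p. The gene with the smallest interaction p and the sex-linked genes on each array completed the rule.

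The alternatives planned were quantile normalization with values floored at 1, normexp background correction with an offset of 50, median scaling, cyclic loess and no filter. They also included the mean of a gene's probes, every probe by itself, an intensity trend with a robust prior, array weights, age as a covariate and the replicate number as a block. Leaving out each array in turn, the arrays of 4 months alone, an estimated inter-gene correlation, the fry test and lists without shared genes were also planned. So were filters on detection p and a slide or chip as a block, which were not run because the values used carry neither, and the series values as an alternative, which became the main values. Quantile normalization with 16 added, 50 or 4 added in place of 16, filters on the noise limit, the removal of failed probes and the removal of tumor 1 with control 2 were chosen after seeing the data.

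The steps were tested on simulated data with the 11413 units and the spread of the real arrays, in which 200 units were changed. For tumor against control, 22.4% of the changes of 1 log2 unit, 89.6% of those of 2 and 100% of those of 4 were recovered, with 11 false calls. For the interaction of age and tumor, 2% of the changes of 2 log2 units and 69% of those of 4 were recovered, with 8 false calls. Each gene was drawn independently with the same spread in both groups, without a lowest value and without failed probes. The 200 changed units are far fewer than the 5064 called in the real data. Recovery and false calls may therefore differ in the real comparison. Of 40 simulated lists without a shift, 0 had a camera p under 0.05, in data whose genes were drawn independently.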

Results

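Gene expression was measured in 4 kidney tumors from mice that carry a Lin28 transgene and in 4 control kidneys, with 1 array for each sample. Lin28 is an RNA-binding protein that blocks the maturation of let-7 microRNAs, and Wilms tumor is a kidney cancer of childhood whose tissue resembles the embryonic kidney. The tumor and the control with number 1 came from animals of 5 weeks, and those with numbers 2 to 4 from animals of 4 months. Values are background-subtracted intensities that the authors scaled to an equal mean on every array. Between 44.2% and 55.3% of the probes of an array were above background, and 11413 genes and unnamed probes were bright enough to be tested.

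The first comparison asked which genes differ between the tumors and the control kidneys. In the tumors, most measured genes of embryonic nephron progenitors, of DNA replication and mitosis, of stroma and of ribosomes rose. Most measured genes of the proximal tubule, of fatty acid oxidation and of mitochondrial respiration fell. These statements rest on single genes, since list tests called 16 of 32 lists with a preset correlation, 0 with an estimated correlation and 20 with fry. Wt1, a transcription factor of the developing kidney that is mutated in some Wilms tumors, had a mean intensity of 3099 ± 627 (SD, n = 4) in tumors and 163 ± 54.6 (SD, n = 4) in controls. This is a rise of 4.16 ± 0.27 (SE) on the log2 scale, or 17.8-fold (limma adjusted p = 4.32e-05). In all, 3677 genes rose and 1387 fell, together 5064 of 11413 (44.4%), of which 2358 rose and 973 fell at least 2-fold (3331 in all, or 1886 with normexp correction and quantile normalization). The groups did not overlap for 4598 genes (40.3%), where chance gives 2.86%. Markers of sex differed between the groups as well, so differences by sex cannot be told apart from differences by tumor here.

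The balance of rises and falls depended on the scaling. With the authors' scaling 72.6% of the changed genes were higher and the median gene was 0.35 log2 units higher in tumors. With cyclic loess 2141 genes rose and 2135 fell (50.1% higher, median gene -0.01). With the arrays scaled to the same median 1870 rose and 2586 fell (42.0% higher, median gene -0.11). With quantile normalization and values floored at 1, 2160 rose and 1720 fell (55.7% higher), and with normexp correction before it 2342 rose and 1849 fell (55.9% higher). With quantile normalization and 16 added, a setting chosen after seeing the data, 2390 rose and 1921 fell (55.4% higher). Medians of gene lists are therefore given relative to the median of all genes unless they are called fitted, and changes of single genes as fitted. The scaling does not move all genes alike, so no fixed amount corrects for it. The relative median of cytosolic ribosomal proteins was 0.79 with the authors' scaling and 1.36 with cyclic loess. That of oxidative phosphorylation and the citric acid cycle was -1.26 and -0.95.

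**Figure D1:**
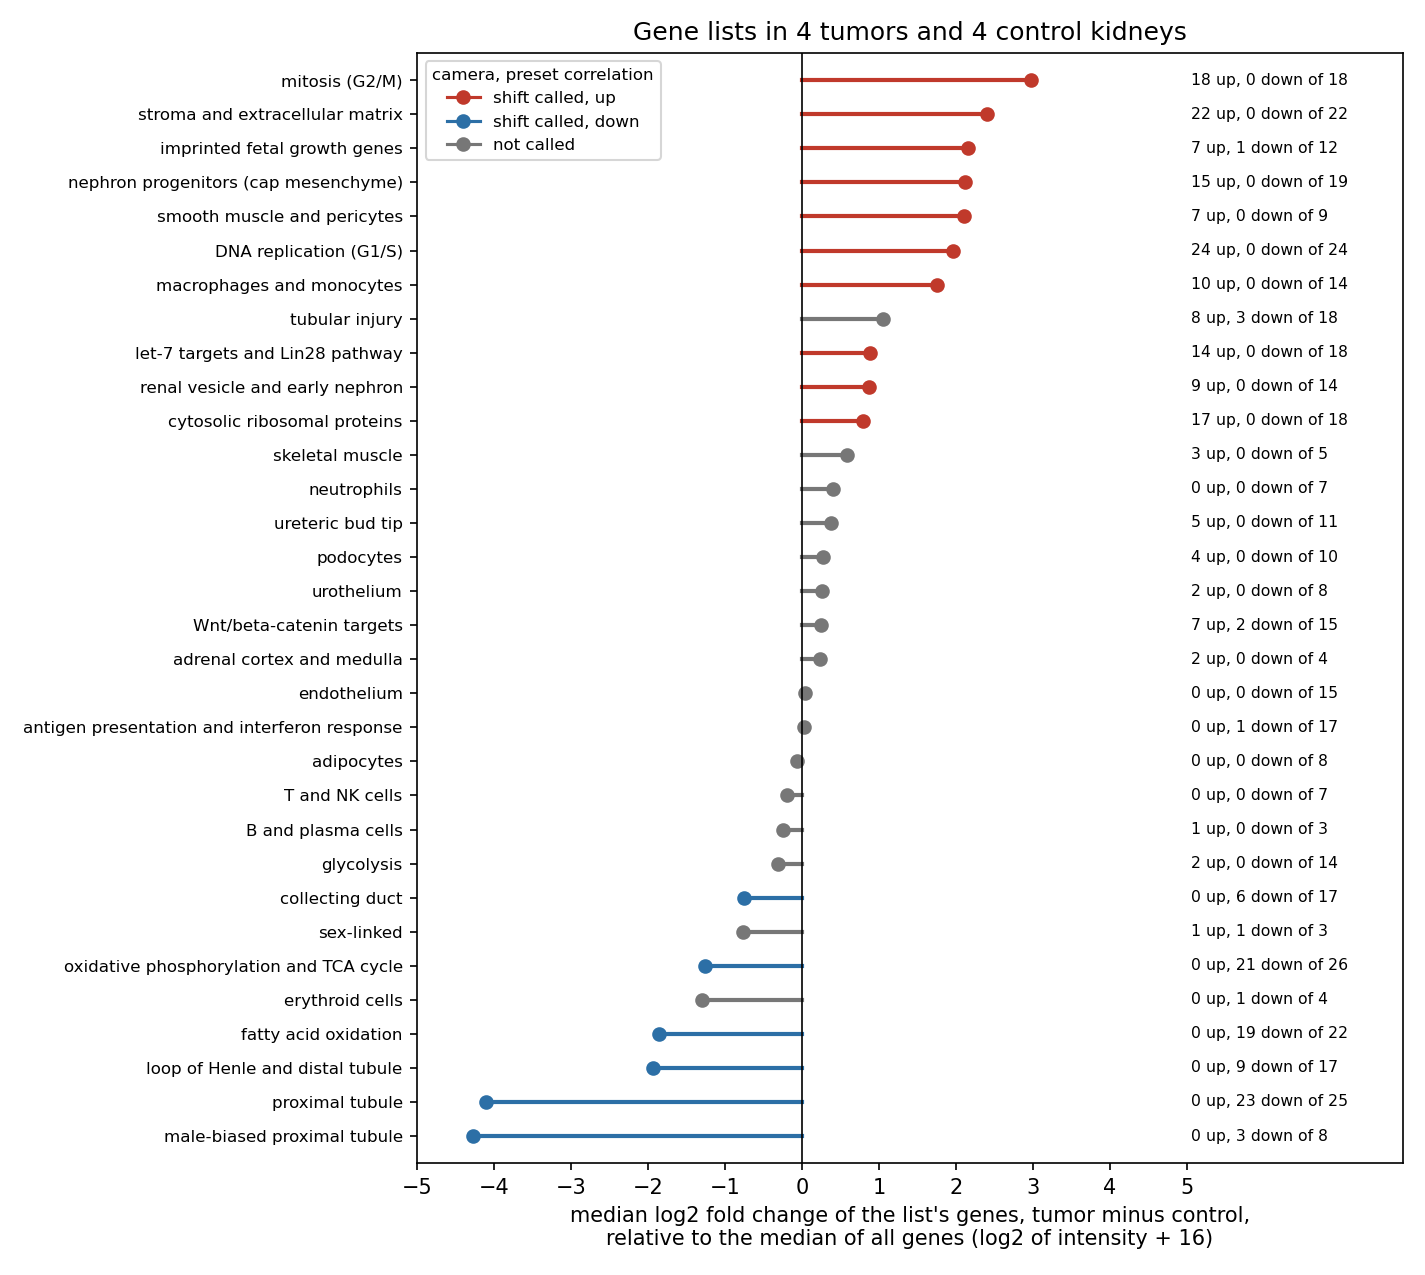
Median log2 fold change of the genes of each fixed list, tumor minus control, relative to the median of all genes (x axis, log2 units; y axis, lists), over 4 tumors and 4 control kidneys. Colours mark lists whose shift was called by camera with the preset correlation, and the counts give members that rose and fell, so that the mitosis list lies at 2.97 and the proximal tubule list at -4.11.

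Nephron progenitors are the self-renewing cells of the embryonic kidney's cap mesenchyme, which are used up around birth in the mouse. Of their 19 measured genes 15 rose and 0 fell (17 rose when adjusted over the list alone), and the median of the list was 2.11 relative to all genes. The shift of the list was called with camera's preset correlation (adjusted p = 2.80e-05) and lost when the correlation was estimated (adjusted p = 0.422 with an estimated correlation). Six2, which keeps these cells in the undifferentiated state, had a mean intensity of 173 ± 135 (SD, n = 4) in tumors and -3.85 ± 4.93 (SD, n = 4) in controls, all of which were at or under background. The difference was at least 9.90-fold (adjusted p = 0.00251). Cited1, a marker of the earliest of these cells, rose by 2.46 ± 0.35 log2 units (adjusted p = 0.00111). Capn6 rose by 5.13 ± 0.42 log2 units. Gdnf, the signal with which the mesenchyme draws out the ureteric bud, was at least 32.9-fold higher, although a second probe for Gdnf differed by -0.04. Hoxc10, Pax2, Sall1 and Robo2 were the 4 members that did not pass.

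Genes of the renal vesicle, the first epithelial stage of the nephron, included 9 rises and 0 falls among 14 (also 9 adjusted over the list alone), with a relative median of 0.87. Hey1, a target of Notch signalling, rose by 3.67 ± 0.26 log2 units and Bmper, a regulator of BMP signalling, by 3.58 ± 0.35. The shift was called (adjusted p = 0.00547; adjusted p = 0.422 with an estimated correlation), but not when only genes above background on all 8 arrays were used (adjusted p = 0.296). Of 11 genes of the ureteric bud tip 5 rose and 0 fell (6 adjusted over the list alone), and the list as a whole was not called (relative median 0.37, adjusted p = 0.158). Among them Etv4 was at least 22.8-fold higher.

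Of 18 measured targets of let-7 and members of the Lin28 pathway 14 rose and 0 fell (14 adjusted over the list alone). The relative median was 0.89 (adjusted p = 0.00293; adjusted p = 0.422 with an estimated correlation). Igf2bp1, a fetal RNA-binding protein and let-7 target, rose by 2.55 ± 0.48 log2 units (adjusted p = 0.00379), from a mean intensity of 39.0 ± 20.3 to 331 ± 202 (SD, n = 4 each). Igf2bp3 rose by 1.26 ± 0.21 log2 units (adjusted p = 0.00256; a second probe differed by 0.62) and Ccnd2, a cyclin of the G1 phase, by 2.87 ± 0.49. Lin28a read 8.48 ± 2.60 in tumors and 3.63 ± 4.69 in controls (SD, n = 4 each), which is at or under background on all 8 arrays. Whether the probes for Lin28a match the transcript of the transgene is not given in the sources used here, so this value does not check the labels. Hmga2 and Mycn were also at or under background in both groups and were not tested. Lin28b, Igf2bp2 and H19 were not analysed here.

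Of 12 imprinted genes of fetal growth 7 rose and 1 fell (8 and 1 adjusted over the list alone), with a relative median of 2.16 (adjusted p = 0.0328; adjusted p = 0.422 with an estimated correlation). The shift of this list was not called without tumor 1 (adjusted p = 0.0570, relative median 2.20), on the arrays of 4 months alone (0.0550), with age as a covariate (0.0554), with the mean of a gene's probes (0.0559), without genes shared between lists (0.0565) or with array weights (0.0717). Mest, which is active on the paternal copy, rose by 5.89 ± 0.37 log2 units, with a mean intensity of 1454 ± 763 in tumors (SD, n = 4), while 3 of the 4 controls were under background, so the size of the rise depends on the value added. Igf2, a fetal growth factor, rose by 4.34 ± 1.24 log2 units (adjusted p = 0.0210), from 1663 ± 3081 to 7467 ± 4248 (SD, n = 4 each). Control 2 read 6283 for Igf2, above tumors 1 and 2, while the other 3 controls read 67.9, 78.4 and 222. The call for Igf2 was lost when any 1 of controls 1, 3 and 4 or of tumors 3 and 4 was left out (change 3.68 to 4.28, adjusted p = 0.0507 to 0.0607), with no filter (0.0679) and at 4 months alone (0.0705). Phlda2, which restrains placental growth, fell by 2.91 ± 0.47 log2 units.

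Of 15 targets of Wnt and beta-catenin signalling 7 rose and 2 fell (8 and 2 adjusted over the list alone), and the list was not called (relative median 0.24, adjusted p = 0.369). Axin2, a feedback inhibitor, rose by 2.88 ± 0.39 log2 units and Tnfrsf19 was at least 9.95-fold higher, while Notum, another inhibitor of the pathway, fell by 1.35 ± 0.36. A second probe for Tnfrsf19 differed by 0.34.

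All 24 measured genes of DNA replication rose (24 adjusted over the list alone), with a relative median of 1.95 (adjusted p = 1.30e-10; adjusted p = 0.422 with an estimated correlation). All 18 measured genes of mitosis rose too (18 adjusted over the list alone), with a relative median of 2.97 (adjusted p = 1.19e-11; adjusted p = 0.422 with an estimated correlation). Mcm5, a subunit of the replicative helicase, rose by 3.52 ± 0.27 log2 units, from a mean of 70.6 ± 20.2 to 994 ± 304 (SD, n = 4 each). Uhrf1, which maintains DNA methylation, rose by 4.21 ± 0.36, although a second probe for it differed by 0.33. Top2a, the topoisomerase of dividing cells, rose by 4.97 ± 0.31 log2 units from 8.20 ± 8.33 to 732 ± 206, and Prc1, a protein of the central spindle, by 4.35 ± 0.28. The 5 largest rises with no overlap between groups were histone H2A genes: H2ac7 (6.39 ± 0.34), H2ac15 (6.16 ± 0.29), H2ac12 (6.01 ± 0.30), H2ac22 (5.99 ± 0.27) and H2ac10 (5.97 ± 0.28). Their probes cover near-identical sequences, so it is uncertain which of the copies each probe measures.

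The proximal tubule, which reabsorbs most of the filtered solutes, had 25 measured genes, of which 23 fell and 0 rose (24 adjusted over the list alone). The relative median was -4.11 (adjusted p = 2.93e-13; adjusted p = 0.422 with an estimated correlation). Gatm and Pck1 were the 2 members that did not pass. Cyp4b1 fell by 5.22 ± 0.90 log2 units, or 37.2-fold, from a mean intensity of 7941 ± 7029 (SD, n = 4) in controls. Kap, an androgen-regulated protein of the proximal tubule, fell by 5.60 ± 1.52 log2 units (adjusted p = 0.0166; 0.0567 with no filter). The level of Kap was 8051 in tumor 1 and 64.7, 19.1 and 60.8 in tumors 2 to 4, against 3959 to 14872 in controls. Among the 5 largest falls with no overlap between groups, Cyp2a5 fell by 6.44 ± 0.91 (3 other probes -6.41 to -3.15) and Dnase1 by 6.22 ± 1.37, and the glycosyltransferases Ugt3a1 and Ugt3a2 fell by 6.07 ± 1.30 and 5.81 ± 1.47. Cyp2d9, at or under background in all 4 tumors, was at least 99.9-fold lower.

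The other segments of the nephron had smaller falls. Of 17 genes of the loop of Henle and distal tubule 9 fell and 0 rose (9 adjusted over the list alone), with a relative median of -1.94 (adjusted p = 5.91e-07; adjusted p = 0.422 with an estimated correlation). Egf, which the distal tubule secretes, fell by 5.16 ± 1.35 log2 units (adjusted p = 0.0145; 0.0506 with no filter) and Pvalb, a calcium-binding protein of the distal convoluted tubule, by 5.15 ± 1.27. Tumor 1 was again apart, with 3066 for Egf and 1459 for Pvalb, while tumors 2 to 4 read at most 60.5 and 33.8. Of 17 genes of the collecting duct 6 fell and 0 rose (5 adjusted over the list alone), with a relative median of -0.76 (adjusted p = 0.00626; adjusted p = 0.500 with an estimated correlation). Without tumor 2 the relative median of the collecting duct was -0.46 (adjusted p = 0.0173), and with array weights the list was not called (adjusted p = 0.0717). The water channel Aqp4 fell by 4.37 ± 0.40 log2 units. The anion exchanger Slc26a4 fell by 2.51 ± 0.89 (adjusted p = 0.0466), a call that was lost when any 1 array except tumor 1 was left out (change -2.86 to -1.74, adjusted p = 0.0537 to 0.113). Of 10 podocyte genes 4 rose and 0 fell (4 adjusted over the list alone). The list was not called (relative median 0.27, adjusted p = 0.201; adjusted p = 0.541 with an estimated correlation), except without tumor 4 with the preset correlation (0.41, adjusted p = 0.0241). Among them Foxc2, a transcription factor, was at least 12.2-fold higher, and Ptpro, a receptor phosphatase, rose by 2.14 ± 0.49 (second probe 0.75).

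Markers of the animals' sex also differed between the groups, so sex may be confounded with group. Calls between tumors and controls cannot be split into an effect of tumor and one of sex. Xist, the RNA of the inactive X chromosome in females, rose by 3.13 ± 0.33 log2 units (adjusted p = 3.24e-04), with intensities of 213, 155, 223 and 301 in tumors 1 to 4 and from 2.20 to 34.8 in controls, the highest of which was control 2. Kdm5d, a gene of the Y chromosome, read 44.9, 44.7 and 53.7 in controls 1, 3 and 4, -5.60 in control 2, and 4.60, 1.00, -0.40 and 2.80 in tumors 1 to 4. Kdm5d was at least 1.19-fold lower in tumors (adjusted p = 0.0365), a call lost when any 1 array except tumor 1 and control 2 was left out (adjusted p = 0.0710 to 0.0970). The call for Kdm5d was also lost with quantile normalization floored at 1 (adjusted p = 0.0560), with normexp correction (0.0776), with no filter (0.0907) and at 4 months alone (0.102). With 4 added, a setting chosen after seeing the data, it was lost too (adjusted p = 0.0561). Uty, also on the Y chromosome, differed by -0.43 ± 0.30 and did not pass (adjusted p = 0.278). Uty passed with arrays scaled to the same median (-0.88, adjusted p = 0.0470), with cyclic loess (-0.89, 0.0374), with array weights (-0.73, 0.0111) and without tumor 1 and control 2, a setting chosen after seeing the data (-0.78, 0.0359). Eif2s3y was at or under background on every array. Of the 3 tested genes of this list 1 rose and 1 fell (also 1 and 1 adjusted over the list alone). The list was not called (adjusted p = 0.715), with a fitted median of -0.43 and a mean of 0.46. Of 8 genes of the proximal tubule that are known to be higher in males 3 fell and 0 rose (5 adjusted over the list alone). Their relative median was -4.28 (adjusted p = 1.96e-04; adjusted p = 0.422 with an estimated correlation), and Kap and Cyp4b1 belong to this list as well.

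**Figure D2:**
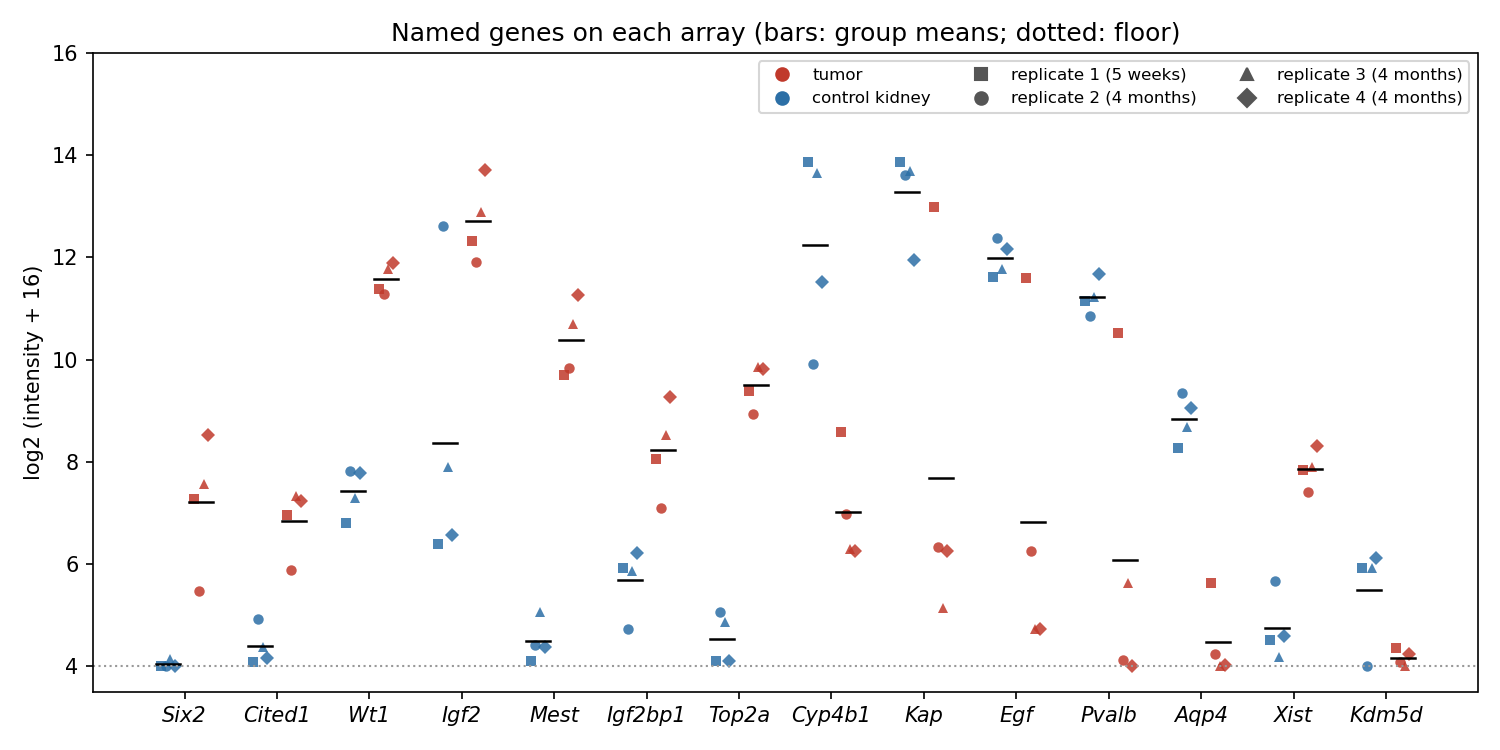
Level of 14 named genes on each array, as log2 of intensity plus 16 (y axis), in control kidneys (blue) and tumors (red), with group means as bars and the lowest possible value as a dotted line. Tumor 1 lies near the controls for Kap, Egf and Pvalb, and control 2 lies with the tumors for Igf2.

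Of 22 genes of fatty acid oxidation 19 fell and 0 rose (19 adjusted over the list alone), with a relative median of -1.86 (adjusted p = 3.34e-13; adjusted p = 0.422 with an estimated correlation). The peroxisomal enzymes Acaa1b and Ehhadh fell by 3.82 ± 0.77 and 3.72 ± 0.82 log2 units. Of 26 genes of oxidative phosphorylation and the citric acid cycle 21 fell and 0 rose (23 adjusted over the list alone). Their relative median was -1.26 (adjusted p = 2.93e-13; adjusted p = 0.422 with an estimated correlation). Ogdh, a dehydrogenase of the citric acid cycle, fell by 1.81 ± 0.28 and Sdhb, a subunit of complex II, by 1.57 ± 0.37 (2 other probes -1.37 and -0.40). Of 14 genes of glycolysis 2 rose and 0 fell (1 adjusted over the list alone), and the list was not called (adjusted p = 0.333). Its fitted median of 0.04 and mean of 0.30 were above 0 while the test pointed down. Hk2, a hexokinase, rose by 4.28 ± 0.49 log2 units. Pkm, pyruvate kinase, rose by 1.30 ± 0.46 (adjusted p = 0.0476), a call lost when any 1 array except tumor 1 and control 2 was left out (adjusted p = 0.0658 to 0.126) and with the arrays scaled to the same median (0.84, adjusted p = 0.159). Of 18 genes of cytosolic ribosomal proteins 17 rose and 0 fell (17 adjusted over the list alone), with a relative median of 0.79 (adjusted p = 6.91e-06; adjusted p = 0.422 with an estimated correlation). Rplp0 rose by 2.70 ± 0.32, although a second probe for it differed by 0.50.

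All 22 measured genes of stroma and extracellular matrix rose (22 adjusted over the list alone), with a relative median of 2.40 (adjusted p = 4.38e-07; adjusted p = 0.422 with an estimated correlation). The matrix proteoglycan Lum rose by 4.65 ± 0.65 log2 units and the collagen Col1a1 by 4.60 ± 0.39, from 47.2 ± 17.0 to 1667 ± 1027 (SD, n = 4 each). Of 9 genes of smooth muscle and pericytes 7 rose and 0 fell (7 adjusted over the list alone), with a relative median of 2.11 (adjusted p = 0.0146; adjusted p = 0.500 with an estimated correlation). With array weights this list was not called (adjusted p = 0.0551). Its member Actg2 was at least 13.9-fold higher (adjusted p = 0.0169), a call lost with normexp correction (1.99, adjusted p = 0.0890) and with no filter (0.0562). Of 5 measured genes of skeletal muscle 3 rose and 0 fell (3 adjusted over the list alone), Tnni2 by 1.49 ± 0.24, and the list was not called (relative median 0.59, adjusted p = 0.230). The list of neurons and glia had only 2 measured members and was not tested, and both rose, Elavl4 at least 2.74-fold and Mbp by 0.96 log2 units.

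Among immune cells, genes of macrophages were the group that was called. Of 14 measured members 10 rose and 0 fell (11 adjusted over the list alone), with a relative median of 1.75 (adjusted p = 0.0328; adjusted p = 0.691 with an estimated correlation). The call was lost without control 1 (1.56, adjusted p = 0.0509) and without tumor 2 (1.26, adjusted p = 0.0969). Ms4a7, a membrane protein of tissue macrophages, rose by 3.62 ± 0.57 log2 units, and a second probe for it differed by 1.25. For T and NK cells, with limma, 0 of 7 members passed (0 adjusted over the list alone and 0 at an unadjusted p under 0.05), the smallest p being that of Ccl5 (0.95 ± 0.47, adjusted p = 0.131), which passed without control 2 (1.36, adjusted p = 0.0209) and with array weights (1.70, 0.00261). The fitted median of that list was 0.15 and its mean 0.25, and the test pointed down (adjusted p = 0.715). Of 3 genes of B and plasma cells 1 rose, Cd79b by 1.86 ± 0.38 (also 1 adjusted over the list alone). That list was not called (adjusted p = 0.738), with a relative median of -0.25 and a test that pointed up. Of 7 neutrophil genes 0 passed with limma (0 adjusted over the list alone and 0 at an unadjusted p under 0.05), with Csf3r at 0.75 ± 0.41 (4 other probes 0.08 to 0.91; adjusted p = 0.168, or 0.0156 without tumor 1, 0.0412 at 4 months alone and 0.0111 with array weights) and a relative median of 0.40 for the list (adjusted p = 0.738). Of 17 genes of antigen presentation and interferon response 1 fell and 0 rose (0 adjusted over the list alone). The fitted median of 0.37 and mean of 0.30 were above 0 while the test pointed down (adjusted p = 0.706). The fall of H2-K1 by 1.81 ± 0.59 was lost when any 1 array except control 2 and tumor 3 was left out (adjusted p = 0.0662 to 0.0867), and a second probe for it differed by -0.07.

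The remaining lists were not called. Of 18 genes of tubular injury 8 rose and 3 fell (9 and 3 adjusted over the list alone), with a relative median of 1.04 (adjusted p = 0.377), and Timp1, a protease inhibitor, rose by 4.14 ± 0.77. The mean of this list was 8.19 (log2) in control 4 and 6.84 to 7.01 in the other controls. Tumor 2 was above control 4 (8.84), and tumors 1, 3 and 4 were below it (7.83, 8.07 and 7.82). With limma 0 of 15 endothelial genes passed (0 adjusted over the list alone and 1 at an unadjusted p under 0.05), and the vascular growth factor receptor Flt1 had the smallest p (-0.93 ± 0.34, adjusted p = 0.0523; second probe -0.13). Flt1 was called with median scaling (-1.38, adjusted p = 0.0107), cyclic loess (-1.09, 0.0337), normexp (-0.96, 0.0486), an intensity trend (0.0482) and array weights (0.00556), and without tumor 2 (-1.22, 0.0123). It was also called in 2 settings chosen after seeing the data, quantile normalization with 16 added (0.0470) and genes above background on all 8 arrays (0.0428). The fitted median of the endothelial list was 0.38 and its mean 0.23, and the test pointed down (adjusted p = 0.622). Of 4 erythroid genes 1 fell (1 adjusted over the list alone), and the relative median was -1.30 (adjusted p = 0.0584). With the preset correlation the erythroid list was called without tumor 2, control 3 or tumor 4 (adjusted p = 0.0265 to 0.0399), with no filter (0.0397) and with array weights (0.0328). Over all arrays the erythroid list had an adjusted p = 0.422 with an estimated correlation. Its member Klf1 fell by 0.95 ± 0.28, a call lost when any 1 array except tumor 1 and control 2 was left out (adjusted p = 0.0543 to 0.0671). For adipocytes 0 of 8 genes passed with limma (0 adjusted over the list alone and 0 at an unadjusted p under 0.05). The fitted median of that list was 0.28 and its mean -0.02, and the test pointed down (adjusted p = 0.619; adjusted p = 0.877 with an estimated correlation). With the preset correlation the list was called without tumor 2 (relative median -0.85, adjusted p = 0.0340). Car3, a carbonic anhydrase of fat, differed by -2.67 ± 1.60 (adjusted p = 0.201), or by -4.28 without tumor 2 (adjusted p = 0.0156) and -4.47 with array weights (0.00268). Of 4 adrenal genes 2 rose (2 adjusted over the list alone), Mc2r at least 1.21-fold and Pnmt by 1.11 ± 0.29 (relative median of the list 0.23, adjusted p = 0.333), and the call for Pnmt was lost under each of the other scalings (adjusted p = 0.0640 to 0.0855). Of 8 urothelial genes 2 rose (1 adjusted over the list alone), Trp63 by 2.48 and the keratin Krt14 by 2.58 ± 0.87 (relative median of the list 0.26, adjusted p = 0.715). The call for Krt14 was lost when any 1 array except tumor 1 and control 2 was left out (1.72 to 2.66, adjusted p = 0.0540 to 0.0974) and under each of the other scalings (1.47 to 3.44, adjusted p = 0.0762 to 0.126).

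Across these lists 16 of 32 were called with camera's preset correlation, 10 up and 6 down. With an estimated correlation, where genes of a list may move together on an array, 0 were called (1 at an unadjusted p under 0.05), and with fry 20. Fry asks whether the genes of a list change at all, and camera whether they change more than other genes. The adjusted p of 0.422 that many lists share is a tie of the adjustment. The unadjusted camera p of these lists ran from 0.0302 (fatty acid oxidation) to 0.184 (let-7 targets and Lin28 pathway). Setting members at or under background in 1 group at their bounds moved the fitted median from 2.46 to 2.47 for nephron progenitors, from 0.59 to 0.84 for Wnt targets, from 0.15 to 0.35 for T and NK cells and from 0.10 to 0.98 for the 3 genes of B and plasma cells. Medians moved toward 0 from 0.58 to 0.35 for the adrenal list, from -0.43 to -0.25 for sex-linked genes, from 0.93 to 0.75 for skeletal muscle and from 0.61 to 0.51 for podocytes. Array weights raised the count of changed genes from 5064 to 7644.

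The second comparison asked whether the difference between tumor and control was the same at 5 weeks as at 4 months, with 1 pair of arrays at 5 weeks. The tubule genes differed less in that pair. The fitted median change, not taken relative to all genes, of the proximal tubule list was -0.88 in the 5-week pair and -4.77 at 4 months, that of the loop of Henle and distal tubule -0.03 and -2.12, and that of the collecting duct 0.55 and -0.74. Fatty acid oxidation stood at -0.69 and -1.56, and oxidative phosphorylation with the citric acid cycle at -0.53 and -1.22. The difference was called for these 5 lists with the preset correlation (camera adjusted p = 1.89e-18, 1.80e-08, 6.58e-04, 5.40e-04 and 6.51e-05 in that order). None of the 5 was called with an estimated correlation (adjusted p = 0.295, 0.836, 0.892, 0.836 and 0.892 with an estimated correlation). For the other 27 lists the adjusted p was between 0.0551 and 0.995, among them nephron progenitors (fitted medians 2.12 in the 5-week pair and 2.32 at 4 months) and mitosis (3.41 and 3.35).

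**Figure D3:**
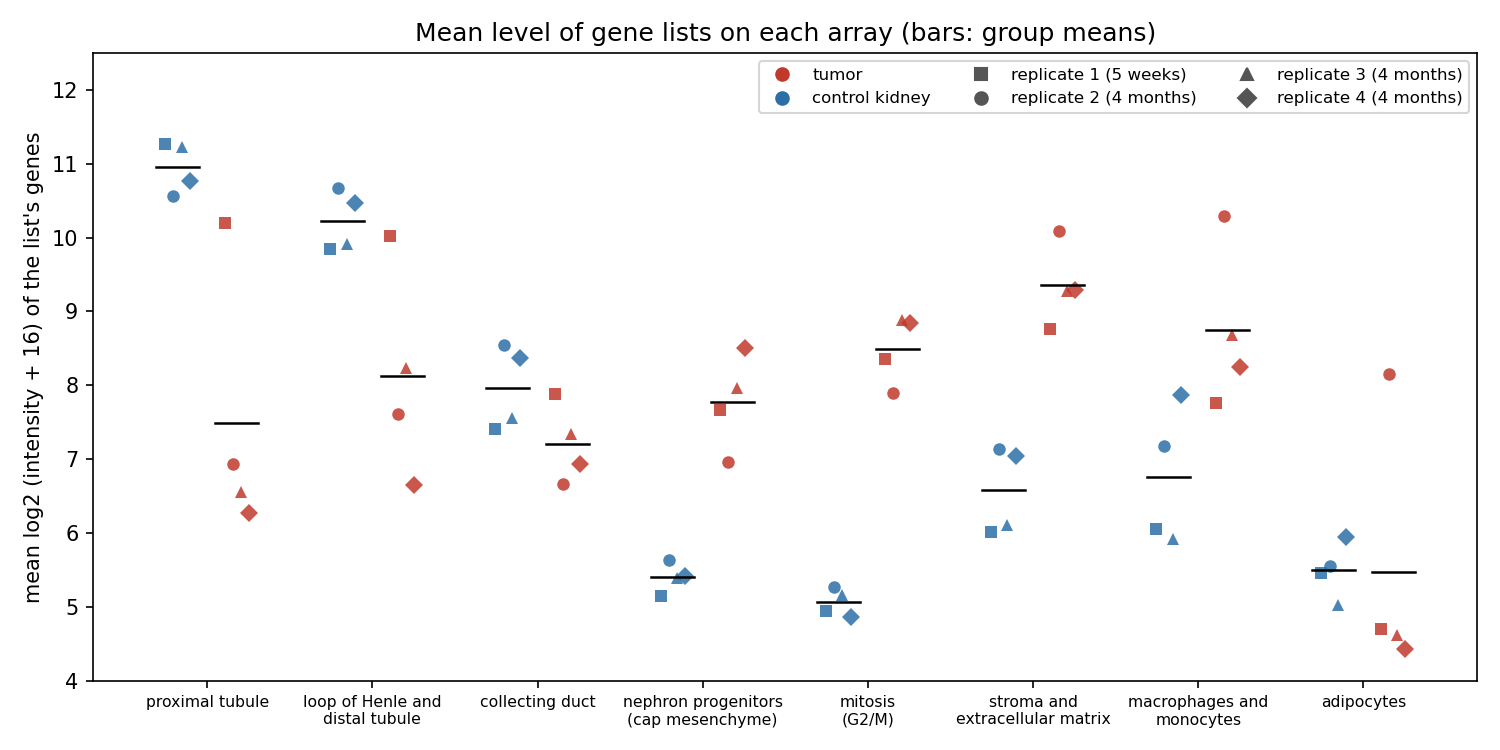
Mean level of the genes of selected lists on each array, as log2 of intensity plus 16 (y axis), in control kidneys (blue) and tumors (red), with group means as bars. Tumor 1, from an animal of 5 weeks, has 10.20 for the proximal tubule list, against 6.27 to 6.93 in the other 3 tumors.

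Over single genes, the limma interaction was called for 169 of 11413, 54 of them higher and 115 lower in the 5-week pair than at 4 months, with 1222 at an unadjusted p under 0.05. The gene with the smallest p was Prdx2, a peroxiredoxin, with a difference of -8.45 ± 0.34 (adjusted p = 4.02e-04). Prdx2 read -16.7 on the array of tumor 1 and 4644 to 6206 on the other 7 arrays, and 2 other probes for it differed by 0.65 and 1.39 between tumors and controls. Between all tumors and all controls Prdx2 differed by -1.85 ± 1.76 (adjusted p = 0.421). On the array of tumor 1, 230 probes lay more than 4 times the noise below 0, and 0 did on the others, and 65 of the 115 lower calls stood on such probes. Without these probes, a setting chosen after seeing the data, 79 genes were called, 34 higher and 45 lower. The count was 401 with quantile normalization floored at 1, 1304 without a filter, 16 among genes above background on all 8 arrays, 96 with array weights and 110 without control 4.

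The third comparison asked whether tumors differ from each other more than control kidneys do. Over the tested genes the correlation between arrays was 0.902 on average within tumors (0.848 to 0.967 over 6 pairs), 0.959 within controls (0.935 to 0.990) and 0.804 between the groups (0.736 to 0.881). The difference between the groups' means was -0.0573 (exact permutation test, two-sided, p = 0.0857 over 70 assignments). The mean levels of tumors and controls differ, and the other assignments mix tumors with controls. This p therefore does not measure whether tumors differ more among themselves, and the question stays undecided. Without control 2 the difference was -0.0709 (exact p = 0.0286), and without tumor 1 it was -0.0136 (exact p = 0.657), with the same limit. The first principal component held 66.2% of the variance and separated the groups, with tumor 1 at -18.1, tumors 2 to 4 between -88.1 and -75.2, and controls between 44.2 and 83.5. On the second component (12.8%) tumor 1 stood at -77.9 and the other arrays between -2.36 and 22.1.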

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

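The splits of the 8 arrays and the test for linked genes in control 2 were set before their results were seen, and the other tests of this part were chosen after.

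In 206 groups of 4 arrays the lowest and the highest array were compared with the rest of their group, and in 17 groups 1 array stood apart, where chance gives about 1 in 20 groups. Tumor 1 held 8 of these places and tumor 2 held 4. The rate of 1 in 20 holds for groups that were not chosen from these data. Many of the genes were named for large changes here, and some belong to the lists compared, as Kap does to the proximal tubule list. The number of places therefore does not measure an excess over chance. On the array of tumor 1, 230 probes lay far below 0, against 0 on the other tumors. Its mean for the proximal tubule list was 10.20 (log2), against 6.27 to 6.93 in the other tumors. It also stood above the other tumors for Cyp2a5 (9.43), Dnase1 (11.06), Ugt3a1 (11.44), Kap (12.98) and Aqp4 (5.63), and for Prdx2 it was at the lowest possible value, 4. Tumor 2 was above the other tumors for smooth muscle and pericytes (9.57, others 7.65 to 7.98), for adipocytes (8.16, others 4.42 to 4.69) and for Car3 (10.69), and below them for H2ac7 (12.05). Control 4 was above the other controls for the tubular injury list (8.19, others 6.84 to 7.01) and for Etv4 (4.69), and below them for Kap (11.96). Control 3 was above the others for Six2 (4.15, others at 4), where all 4 controls are at or under background, as they are for Etv4, so these 2 places are within noise. Control 2 was at the lowest value for Kdm5d (4, others 5.92 to 6.12).

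The effect of tumor differed between the 5-week pair and 4 months by the interaction test in 5 lists and 7 named genes, with 1 tumor at 5 weeks. With an estimated correlation 0 of the 5 lists were called (adjusted p = 0.295 to 0.892). The fitted medians of the difference, in log2 units and not relative to all genes, were 3.32 for the proximal tubule, 2.47 for the loop of Henle and distal tubule and 1.86 for the collecting duct. They were 0.74 for fatty acid oxidation and 0.66 for oxidative phosphorylation with the citric acid cycle. The differences of the genes were 6.85 for Egf, 6.29 for Kap, 6.05 for Pvalb, 5.86 for Ugt3a1, 3.71 for Ehhadh, 3.62 for Cyp2a5 and -8.45 for Prdx2. The value of Prdx2 rests on 1 probe that read -16.7 on tumor 1, set to the lowest possible value, and on a second probe tumor 1 differed from the mean of the other 7 arrays by 0.00482 log2 units.

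Chance in the grouping was examined with the 35 splits of the 8 arrays into 4 and 4. For the changed genes 1 split gave as many (5064), which was the real one, and the highest other split gave 2. Every other split mixes tumors with controls, so the contrast itself widens the spread there and keeps calls few. With 1 of 35 the smallest share that can be reached, these splits do not exclude chance. Chance cannot be excluded either for the number of lists called by camera with the preset correlation. There 7 of the 35 splits gave at least the real 16, and the highest other split gave 19. The 6 others that reached 16 kept 3 tumors on 1 side, so they hold a part of the contrast, and the highest of the 18 splits with 2 tumors on each side gave 15.

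The fall of proximal tubule genes in tumors was weighed with 3 tests. For a different sex of the animals as the whole cause, the list without its male-biased members had a fitted median of -3.34, against -3.76 for the full list on the same scale. Other members may also differ with sex, and the sex markers split nearly as the groups do, so this test cannot decide. The authors' scaling is argued against, since the fitted median closest to 0 over 6 scalings was -3.25. The falls differed between segments, by -2.16 between the proximal tubule and the loop and distal tubule (95% interval -3.16 to -0.53). The gap to the collecting duct was -3.34 (-4.41 to -1.50). These intervals resample the genes of a list and not the arrays, so they do not measure the spread between animals. Whether each member is read from its segment alone was not tested, so the gaps do not decide about an even loss of tubule cells. What stays open is an even loss of tubule cells, a loss of proximal tubule cells beyond that of other segments, a loss of expression within them, and sex.

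In the 5-week pair the lower and the higher genes were weighed apart, and for the 65 of 115 lower genes on failed probes of tumor 1, failed values may be the cause: tumor 1 lay within 1 log2 unit of the mean of the other 7 arrays on 100% of the 13 second probes. Of the other 50 genes, 14 were above background on tumor 1 and 16 had a second probe, of which 87.5% lay that close and 2 did not, so failed values may explain a part of these, and genes without a second probe stay untested. Second probes that themselves lay far below 0 on tumor 1 were left out of these counts, which favours close ones. Among them Eif2s2 read -46.1 and -5.7 on tumor 1 on 2 probes, against means of 160 and 807 on the other 7 arrays. For the genes higher there, kidney tissue of the makeup of control 1 in the sample of tumor 1 would give equal shares of the signal of control 1 in each segment. The shares differed by 0.391 between segments. The intervals resample genes of 1 pair of arrays and not animals, and the proximal tubule list holds male-biased genes, so this does not decide. The shares were 0.482 for the proximal tubule (95% interval 0.339 to 0.586) and 0.872 for the loop and distal tubule (0.650 to 1.58), with the collecting duct at 0.794 (4 genes, 0.111 to 1.53, overlapping both) and the 7 male-biased genes at 0.0194 (-0.00534 to 0.540). Kidney tissue of another makeup stays open too, with a median share of 0.372 over 598 genes (10th and 90th percentiles 0.0704 and 0.811). So does the age of the animals, untested and not separable from tumor 1 with 1 tumor at 5 weeks.

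Control 2 stood apart from its group: 217 genes differed from the other controls on it, 151 higher and 66 lower, against 64 on control 4, 4 on control 3 and 2 on control 1. The median share of the tumor signal in control 2 was small, 0.0286 over 222 genes (95% interval over resampled genes 0.0209 to 0.0361), although Igf2 alone had 0.839. These genes were chosen by calls from a fit that includes control 2, which can leave out genes where it carries tumor signal. A small amount of tumor tissue in the sample therefore stays open. Another sex of the animal stays open, with values on both sides: 62.5% of the 8 male-biased genes were lower in control 2 than in each other control, where chance gives 25%, and Kdm5d was at the lowest value. Xist read 34.8 in control 2, above background there (limit 11.6) and the highest of the controls, but under the 155 to 301 of the tumors. Against another sex, Hsd3b4 (13519, others at most 8451) and Serpina1f (2401, others at most 926) were higher in control 2 than in each other control. Strain variants in linked blocks of the genome stay open, because 46 genes had another such gene within 5 tested genes, more than the mean of 34.2 in 1000 draws. The adjusted permutation p was 0.0999, and the ratio of found to drawn, 1.34, was under that of control 4, 4.29 with 12 genes. Control 4 itself passed this test (adjusted permutation p = 0.0120).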

How the results depend on the processing

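The settings named as added were chosen after seeing the data, and the others before. For settings that moved a count or a call, the cause was not tested unless stated.

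The 5064 changed genes became 7644 with array weights and stayed within 1.5 times otherwise (3642 to 5746 without 1 array). The 16 called lists became 0 with an estimated correlation, by its construction a wider null, and were 14 to 20 otherwise (15 to 18 without 1 array). The 169 genes called in the interaction, which rests on 1 tumor at 5 weeks, became 401 with quantile normalization floored at 1, 1304 with no filter on dim probes and 96 with array weights, and with added settings 16 above the noise limit on all 8 arrays and 79 without the failed probes of tumor 1. Leaving out 1 array at 4 months gave 110 (without control 4) to 175 genes. The spread was -0.0835 to -0.0136 without 1 array, and its exact p passed the threshold only without control 2 (-0.0709, exact p = 0.0286). That p does not measure the spread within groups alone, since the other assignments mix tumors with controls.

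A change of direction was counted as reversed only where the main or the alternative fit was called, and otherwise as the same. Of 1719 values of 65 named genes under 27 alternatives, 1618 were the same by this rule, 78 lost the call and 22 gained it. The 1 that reversed was Prdx2 at 1.39 (adjusted p = 0.0243, another probe) above the noise limit on all 8 arrays. Of 916 values of 32 lists, 880 were the same by this rule, 28 lost the call and 8 gained it, with none counted as reversed. Lists that were not called could change direction. That of B and plasma cells pointed up with the authors' scaling and down with quantile normalization floored at 1 (camera adjusted p = 0.738 and 0.924).

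The replicate numbers were not taken as pairs, since not every equal-numbered pair correlated above 0.1 after group means were removed (0.208, 0.197, 0.113 and 0.0656). Tumors 1, 3 and 4 correlated best with their own number and tumor 2 with control 4 (0.282), a hint from the data alone. With the number as a block 5088 genes and 16 lists were called. The imprinted list (adjusted p = 0.0535) and Slc26a4 (0.0811) lost their calls, and the erythroid list (0.0375) and Flt1 (0.0471) gained one.

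Filters on detection p and a slide block, both planned, were not run, since the values used carry neither. Signal over background (44.2% to 55.3% of probes) limits dim genes.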

Other observations

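The families and genes of this part were chosen after the values were seen, and no test of an explanation was made for them.

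Histone genes were counted by family, with no test of a difference between families. Of 14 H2A genes 13 rose and 1 fell, with a median of 2.82 to 6.09 relative to all genes over 6 scalings. Of 9 H3 genes 7 rose and 0 fell (relative median 1.02 to 2.66). Of 10 H2B genes 2 rose and 4 fell, with a relative median of -1.04 to -0.74, and between 1 and 6 fell over the scalings. Of 10 H4 genes 5 rose and 0 fell with the authors' scaling (2 to 5 rose and 0 to 1 fell over the scalings), and the relative median went from -0.06 to 0.42, so its sign depends on the scaling. Of 3 H1 genes 1 rose and 1 fell. Of 25 Hox genes 14 rose and 0 fell with the authors' scaling (10 to 14 rose and 0 to 2 fell over the scalings, relative median 0.58 to 0.83). Of 19 genes of ribosome assembly 12 rose and 0 fell (6 to 12 rose over the scalings, relative median 0.33 to 0.48). Of 71 genes of mitochondrial ribosomal proteins 1 rose and 15 fell, and between 12 and 40 fell over the scalings, with a relative median of -0.54 to -0.33.

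Of 16 organic ion transporters of the Slc22a family 12 fell and 1 rose (relative median -3.82 to -2.15 over the scalings). Of 8 Ugt glucuronosyl- and glycosyltransferases 6 fell and 0 rose (-4.50 to -2.65). Of 38 cytochrome P450 genes 14 fell, 2 rose and 22 did not pass (-2.09 to -0.97). Of 30 collagen genes 21 rose and 1 fell (0.87 to 2.14).

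Single tumors held genes that no other array showed at a similar level. On tumor 3 the secretory genes Svs5 (9977, highest other array 14.3), Pate4 (12035, other 21.9), Svs4 (3992, other 9.10) and Svs2 (1177, other 2.90) and the defensin Defb20 (476, other 9.90) were high. Svs genes are known from the seminal vesicle, a male gland, while the same array read 223 for Xist and -0.40 for Kdm5d. Whether RNA of another tissue or sample was present on that array was not tested, and this leaves its values in doubt to an unknown extent. On tumor 2, 55 genes were at least 2 log2 units above every other array, among them Arg1 (2895, other 78.3), Fos (2233, other 127), Rgs1 (541, other 21.1), Fosb (367, other 11.4), Gpnmb (1970.1, other 147) and Hp (1353, other 102). On tumor 1 Havcr1, a marker of tubular injury, read 863 (other 169). On control 4 the fibrinogen genes read 3921 for Fgg (other 373) and 5271 for Fga (other 666).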
